A study of Mus musculus with 12 samples.

How the data were processed

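Gene expression in mouse lung was measured by RNA sequencing in 12 libraries, 3 for each combination of genotype (WT or Has2+/-) and treatment (saline or ovalbumin). Per the labels, lungs of C57BL/6 mice were flash frozen, RNA was extracted with Trizol, 500 ng went into stranded libraries, and sequencing was done on a NextSeq500; rRNA depletion and poly-A purification are both named. The titles of the ovalbumin samples give a time of 24 without a unit. The submitters' processing notes name the mm10 genome build, and the aligner and the counting program are not given in the sources used here.

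The signal values used here are the authors' normalized expression values, which the file headers give no further description of. From the values themselves, they are gene counts that the authors quantile-normalized over the 12 libraries: sorted from low to high, the 12 columns are identical (largest difference 0), every value is a multiple of 1/12 within 1e-06, and each column sums to 6852201. The table holds 49585 genes, of which 30723 are listed at 0 in each library. Genes with tied counts took consecutive values in the order of the table, so that up to 783 genes per library with no reads carry a value above 0 (at most 0.917). Because the columns were forced to one distribution, the depth of each library is unknown, and no counting interval was computed. Small values are imprecise, as the order of ties shows: genes with no reads reach at most 0 to 0.917 units, depending on the library. The genes that had 10 reads sit at a mean of 8.49 to 12.6 units, also depending on the library. A neighbouring set of columns is the log2 of the same values plus 0.1 and was not used. The score columns are fold changes between pairs of groups from the authors' EDGE test with tagwise dispersions, per the file headers. These fold changes carry a sign. The headers do not say which group is set against which, and the second group named was read as set against the first. The p-value columns are that test's FDR-corrected p-values, also per the file headers. Both kinds of column are quoted only in the closing section.

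Columns carry codes for genotype and treatment, which were read as the groups named in the sample titles, and a running library number from 1 to 12 that matches no title. Libraries were therefore assigned to groups and to no individual sample, and no pairing between groups was made. Replicates were checked against each other: Spearman correlations across genes were 0.971 to 0.990 within groups and 0.954 to 0.990 between them. Library 3 (WT ovalbumin) correlated at 0.971 and 0.974 with libraries 1 and 2 of its group and at 0.984 with WT saline library 4. Library 12 (Has2+/- saline) correlated at 0.979 and 0.981 with libraries 10 and 11 of its group. With WT saline library 5 and Has2+/- ovalbumin library 8 it correlated at 0.988 and 0.987. Libraries 3 and 12 were thus closer to some libraries of the other treatment or genotype than to those of their own group. At most 4.46% of the tested genes had identical values in 2 libraries, so none is a copy of another. Xist, expressed in females, was present in all 12 libraries. Genes were matched by identifier to GENCODE release M21 (49326 of the identifiers, 45128 with identical coordinates), which gave positions, transcript GC content and transcript length.

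The design, the gene lists, the rule for naming genes and the alternatives in the first group below were fixed before the data were examined. The design chose between a model for read counts and limma by the unit of the table; since the values are not counts, limma 3.58.1 in R 4.3.3 was used on log2(value + 1), with the trend and robust options of its empirical Bayes step, on the 19017 genes with a mean of at least 1 in at least 1 group. All 12 libraries were fitted together with 1 mean per group and no covariate (8 residual degrees of freedom, median prior 8.40). The comparisons were ovalbumin with saline in WT and in Has2+/-, Has2+/- with WT under saline and under ovalbumin, the interaction of genotype and treatment (the Has2+/- change minus the WT change) and the genotype difference averaged over treatments. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison with a threshold of 0.05. The overlap of the ovalbumin responses was counted per direction beside the number expected from independent calls.

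The 32 fixed lists (14 of functions and 18 of cell types, 369 distinct genes) were counted over all genes and adjusted over the list alone, and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 3 tested members, and again with an estimated correlation. With the preset value 18, 17, 9, 14, 9 and 6 lists passed in the 6 comparisons, in the order above; with the estimated one 0 passed in each, the smallest adjusted p being 0.0818, 0.0770, 0.109, 0.470, 0.0594 and 0.397. Ear11 of the alternative macrophage list was not found in the table. A list of 13 squamous epithelium genes was added after the data were seen. Genes were named by this rule: Has2 always; in each comparison the 8 largest rises and 8 largest falls among genes past the threshold whose libraries do not overlap (a condition not set for the interaction) and whose higher group has a mean of at least 1, leaving out unnamed loci, pseudogenes and antigen receptor segments; and of each list at most 3 members per direction with the smallest p, or all that passed in the hyaluronan list. The text gives these genes in part and summarises the rest by counts.

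Each result was recomputed with 1 choice changed at a time. The alternatives fixed beforehand were quantile normalization within limma, no filter beyond a value above 0, a group mean of at least 5, a pseudocount of 0.1, limma without its trend and robust options, only the groups compared in the fit, an absolute log2 change of at least 1, and each library left out in turn. Chosen after seeing the data were the mean log2 level of the squamous list as a covariate, leaving out libraries 3 and 12 together, rescaling by median-of-ratios factors, averaging tied genes up to 20 reads, a pseudocount of 10, and removing from each library its trend against transcript GC content and log length (splines with 5 degrees of freedom). With rescaling and with the covariate, the median change of all genes lay within 0.036 of 0 in each comparison. To see how often chance gives as many calls, the libraries were also split in other ways into groups of the same sizes, in all 10 ways for 3 against 3 and in 100 ways drawn with a fixed seed for the interaction and the average.

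The procedure was tested on simulated data of the same size and of the typical spread at each level, normalized as the authors did. Only a small share of genes was changed, all of them at higher mean values, and each gene varied independently of the others. The rates below therefore do not cover genes at low values, Has2 among them. Nor do they cover variation that many genes share, such as that of a second tissue. In the comparison of 3 with 3 libraries it recovered 34.7% of genes changed 1.25-fold, 80% at 1.5-fold, 97.3% at 2-fold and 100% at 4-fold (150 genes each over 3 simulations), with 6.96% false calls, and made 0 calls where nothing had been changed. With a GC trend added to the simulated libraries, removal of the trend lowered the number of unchanged genes called from 5533 to 77 and kept all 200 genes changed 4-fold. Other tests were Fisher's exact test and an exact permutation test in scipy 1.17.1; tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The deposited comparisons across both genotype and treatment at once were left out, because they mix both effects.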

Results

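RNA from the lungs of C57BL/6 mice was sequenced in 12 libraries that fall into 4 groups of 3. The mice were wild type (WT) or labelled Has2+/-, heterozygous for a loss of Has2. This gene encodes an enzyme that makes hyaluronan, a large sugar polymer of the extracellular matrix. Each genotype was given either saline or ovalbumin, a protein allergen to which mice can be sensitized so that a later exposure of the airways inflames the lung. The libraries are numbered in the order of the deposited table: 1 to 3 are WT with ovalbumin, 4 to 6 WT with saline, 7 to 9 Has2+/- with ovalbumin, and 10 to 12 Has2+/- with saline. The table lists 49585 genes as normalized read counts, on a scale the authors forced to be identical in all 12 libraries, with a sum of 6852201 in each. The depth of each library is therefore unknown, and no counting interval was computed. Values below are in these normalized units, as the mean ± SD of the 3 libraries of a group (n = 3). Changes are log2 differences of the value plus 1, tested with limma over 19017 genes. The labels do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples.

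Has2 itself (ENSMUSG00000022367, chromosome 15, 56665627 to 56694539 in mm10, minus strand), the synthase gene after which the mice are named, was measured at a low level in every group. It stood at 5.72 ± 1.17 in WT saline and 6.72 ± 3.39 in WT ovalbumin libraries (SD, n = 3). In the libraries labelled Has2+/- it stood at 7.75 ± 0.382 with saline and 7.89 ± 2.95 with ovalbumin, which was not lower than in WT. The difference averaged over both treatments was 0.32 (95% confidence interval -0.28 to 0.93, adjusted p = 0.684), an interval that leaves out the -0.81 that a level at 50% of WT would give on this scale. Which part of the gene the deficient allele lacks is not stated in the labels, and a gene-level value counts reads over all its exons. The level of Has2 therefore leaves open whether the genotype codes of the columns are right, and every comparison of genotypes below rests on them. The other hyaluronan synthase genes, Has1 and Has3, had group means of 21.5 to 30.8 and of 74.2 to 119.

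The first comparison asks how ovalbumin changed the lung transcriptome of WT mice. Chemokines of type 2 immunity, mucus products and genes of alternatively activated macrophages rose together. Ccl11 (eotaxin), which attracts eosinophils, rose from 19.4 ± 2.25 to 103 ± 35.8 (SD, n = 3; log2 change 2.28, adjusted p = 0.000118). Ccl8 and Ccl22, ligands of chemokine receptors on T helper cells, rose by 3.93 (adjusted p = 0.000479) and 1.86 (adjusted p = 0.00164). Of the 12 tested genes of the type 2 cytokine and chemokine list 6 rose (7 adjusted over the list alone), and 3 did without library 1 or without library 6. Camera placed the list above the other genes (adjusted p = 4.69e-05, but adjusted p = 0.151 with an estimated correlation).

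Of 13 genes of the goblet cell list 8 rose (10 adjusted over the list alone). Its camera adjusted p was 4.18e-09 (adjusted p = 0.0818 with an estimated correlation). The gel-forming mucin Muc5ac rose from 57.7 ± 12.1 to 625 ± 333 (SD, n = 3; 3.27, adjusted p = 0.00341). Its folding partner Agr2 rose by 3.22 (adjusted p = 0.00158) and Spdef, a transcription factor of mucous cells, by 1.53 (adjusted p = 0.00471). Clca1, a secreted goblet cell protease, went from 103 ± 77.7 to 3853 ± 2278 (5.45, adjusted p = 0.0134). This call ended without library 1 (adjusted p = 0.0569, within 0.0113 to 0.0569 over 18 alternatives). The libraries named beside a call, here and below, are the single libraries whose omission ended it, and alternatives of another kind ended many of these calls too, within the range given. The alternatives counted here and below include quantile normalization in limma, which left all calls unchanged because the values were already so normalized, and so tests nothing.

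Of 11 genes of the alternative macrophage activation list 7 rose (10 adjusted over the list alone). Here camera gave an adjusted p of 3.92e-09 (adjusted p = 0.0818 with an estimated correlation). The secreted protein gene Retnla rose from 317 ± 32.2 to 7365 ± 1734 (SD, n = 3; 4.51, adjusted p = 0.00136). The lipoxygenase gene Alox15 rose from 29.7 ± 5.80 to 154 ± 6.88 (2.35, adjusted p = 2.34e-05) and the mannose receptor gene Mrc1 from 700 ± 38.4 to 1086 ± 50.1 (0.63, adjusted p = 0.000142). Chil4, a chitinase-like protein gene, rose by 5.41 (adjusted p = 0.0129). Without library 1 it did not pass (adjusted p = 0.0543, within 0.00404 to 0.0543 over 18 alternatives).

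**Figure D1:**
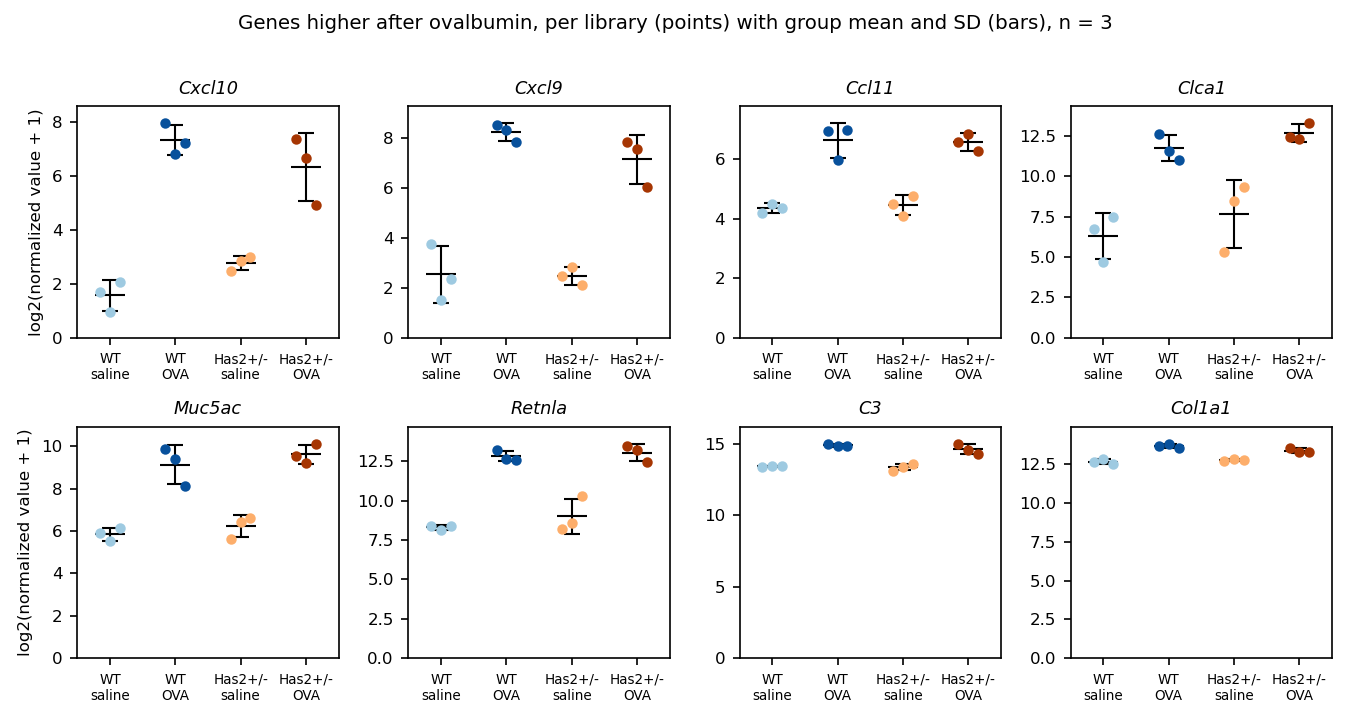
Normalized values of Cxcl10, Cxcl9, Ccl11, Clca1, Muc5ac, Retnla, C3 and Col1a1 in the 12 libraries, as log2(value + 1) on the vertical axis and the 4 groups on the horizontal axis; points are libraries, and lines and bars are the mean and SD of 3 libraries. In WT, Retnla went from 317 to 7365 units and Col1a1 from 6519 to 13111.

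Inflammatory and interferon-induced genes were the other large group of rises in WT lungs. Among the large changes were those of Cxcl10 and Cxcl9, interferon-induced chemokine genes whose products attract T cells. Cxcl10 rose from 2.11 ± 1.13 to 170 ± 69.6 (SD, n = 3; 5.77, adjusted p = 0.000147) and Cxcl9 from 6.14 ± 5.62 to 302 ± 71.7 (5.68, adjusted p = 0.000525). Both start near the lower end of the scale, and over 18 alternatives, pseudocounts included, their log2 changes ran from 3.83 to 6.34 and from 4.30 to 6.29. Of 15 genes of the interferon list 11 rose (15 adjusted over the list alone), but 3, 4 and 2 did without library 1, 5 or 6. The list had a camera adjusted p of 2.88e-12 (adjusted p = 0.182 with an estimated correlation). Mx1, an antiviral GTPase gene, rose by 2.68 (adjusted p = 0.0168), except without library 6 (adjusted p = 0.0631) or with the level of squamous epithelium genes as a covariate (adjusted p = 0.0502, within 0.0136 to 0.0631 over 18 alternatives). Of 14 genes of the proinflammatory list 9 rose (10 adjusted over the list alone). Camera gave it an adjusted p of 1.85e-08 (adjusted p = 0.182 with an estimated correlation). The neutrophil chemokine gene Cxcl2 rose by 3.32 (adjusted p = 0.000647), the monocyte chemokine genes Ccl7 and Ccl2 by 4.35 (adjusted p = 0.00093) and 3.21 (adjusted p = 0.00191), and the acute-phase gene Saa3 by 4.82 (adjusted p = 0.00407). Acod1, which makes itaconate in activated macrophages, rose by 4.39, and Fer1l6 by 4.35 (both adjusted p = 0.0141). The Acod1 call ended without library 1, 4 or 6 (adjusted p = 0.0532, 0.0523 and 0.0550, within 0.00939 to 0.0567 over 18 alternatives). That of Fer1l6 ended without library 1 (adjusted p = 0.0510, within 0.00689 to 0.0542).

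Complement and cell cycle genes rose in WT lungs as well. Of 12 complement genes 8 rose, also adjusted over the list alone, with a camera adjusted p of 8.86e-09 (adjusted p = 0.0818 with an estimated correlation). C3, the central component of the cascade, rose from 11023 ± 98.1 to 30609 ± 1841 (SD, n = 3; 1.47, adjusted p = 0.000681). C1qc and C1qa, which start the classical pathway, rose by 1.49 (adjusted p = 0.000422) and 1.41 (adjusted p = 0.000511). Of 16 cell cycle genes 10 rose (13 adjusted over the list alone), and 5 and 6 did without library 1 or 6. The camera adjusted p was 1.73e-08 (adjusted p = 0.218 with an estimated correlation). The replication genes Rrm2 and Mcm5 rose by 1.80 (adjusted p = 0.000461) and 1.58 (adjusted p = 0.00172), and the kinase gene Cdk1 by 1.46 (adjusted p = 0.00393).

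Matrix genes rose in WT lungs, whereas the hyaluronan list moved in both directions. Of 16 genes of matrix remodelling 12 rose (14 adjusted over the list alone), with a camera adjusted p of 8.61e-12 (adjusted p = 0.0818 with an estimated correlation). Col1a1 and Col1a2, the genes of the type I collagen chains, went from 6519 ± 751 to 13111 ± 1134 (SD, n = 3; 1.01, adjusted p = 2.81e-05) and from 5357 ± 351 to 9238 ± 575 (0.79, adjusted p = 4.32e-05). The membrane collagenase gene Mmp14 rose by 0.78 (adjusted p = 0.000116). In the hyaluronan list 2 of 22 genes rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.533). Vcan, a hyaluronan-binding proteoglycan gene, rose from 178 ± 17.6 to 527 ± 65.1 (1.56, adjusted p = 8.29e-05). Cd44, which encodes the main hyaluronan receptor, rose from 1371 ± 107 to 2049 ± 175 (0.58, adjusted p = 0.00176). Itih5, of the family of heavy chains that bind hyaluronan, fell from 216 ± 48.6 to 89.5 ± 27.5 (-1.28, adjusted p = 0.00365).

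Lists on TGF-beta, sphingosine 1-phosphate and glucocorticoid signalling moved both ways. They were written with knowledge of what a paper on these mice treats, so they are not independent of the study. Of 17 TGF-beta genes 4 rose and 2 fell (5 and 2 adjusted over the list alone). The ligand gene Tgfb1 rose from 798 ± 94.9 to 1198 ± 117 (SD, n = 3; 0.59, adjusted p = 0.00117) and the receptor gene Tgfbr1 by 0.40 (adjusted p = 0.00560). The coreceptor gene Tgfbr3 fell from 1552 ± 81.3 to 968 ± 109 (-0.69, adjusted p = 0.00114). With 1 library left out in turn 4 to 5 TGF-beta genes rose and 1 to 2 fell. The median change of this list was -0.03, its mean 0.08 and its camera direction up (adjusted p = 0.518). Of 12 sphingosine 1-phosphate genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.533). The receptor gene S1pr3 rose by 0.32 (adjusted p = 0.00615), and S1pr4, a receptor gene of lymphoid cells, fell by 0.44 on the log2 scale (adjusted p = 0.00590). The transporter gene Spns2 (-0.22) was the other fall and lost its call without any 1 of the 6 libraries (adjusted p = 0.0602 to 0.107, within 0.0280 to 0.107 over 18 alternatives), so that 1 gene fell in each case. Sgpl1, which encodes the lyase, rose by 0.43 (adjusted p = 0.0108), except without library 1 (adjusted p = 0.0557, within 0.00590 to 0.0557 over 18 alternatives). Of 13 genes of the glucocorticoid list 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.636), and 1 to 2 rose and 1 to 3 fell with 1 library left out in turn. The steroid-induced chaperone gene Fkbp5 rose from 172 ± 20.6 to 309 ± 27.6 (0.85, adjusted p = 0.00222), and the glucocorticoid receptor gene Nr3c1 fell from 1723 ± 28.9 to 1444 ± 37.2 (-0.26, adjusted p = 0.00619).

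Immediate early genes, which cells switch on within minutes of a stimulus, and clock genes also moved. Of 10 immediate early genes 3 rose and 1 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.104). Junb rose by 1.14 (adjusted p = 8.19e-05), and Fosb fell from 76.9 ± 1.92 to 33.6 ± 10.4 (SD, n = 3; -1.22, adjusted p = 0.0134). Of 14 clock genes 3 fell, also adjusted over the list alone (median change 0.24, mean 0.05, camera adjusted p = 0.921). Among them were the positive-arm genes Npas2 (-1.08, adjusted p = 0.000470) and Arntl (-0.83, adjusted p = 0.00615).

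In WT lungs 4 of 7 eosinophil markers rose, also adjusted over the list alone, with a camera adjusted p of 0.00745 (adjusted p = 0.116 with an estimated correlation). They included the eotaxin receptor gene Ccr3 (3.22 ± 1.42 to 28.3 ± 17.8, SD, n = 3; adjusted p = 0.000773). Without library 1, 2, 4 or 6 the eosinophil count was 2, 2, 1 and 2. Of 13 T cell markers 4 rose and 1 fell (8 and 1 adjusted over the list alone), with a camera adjusted p of 0.00121 (adjusted p = 0.334 with an estimated correlation). The costimulator gene Icos rose by 1.51 (adjusted p = 0.00868). Without library 1, 2, 3, 5 or 6 the T cell count of rises was 1, 2, 8, 2 and 1. Of 12 dendritic cell and monocyte markers 3 rose, or 7 without library 3, and 1 fell (6 and 1 adjusted over the list alone). That list had a camera adjusted p of 0.00468 (adjusted p = 0.241 with an estimated correlation). Itgax rose by 1.37 (adjusted p = 0.0101) and the migration receptor gene Ccr7 by 0.52 (adjusted p = 0.00289), while Clec9a, a marker of cross-presenting dendritic cells, fell by 0.60 on the log2 scale (adjusted p = 0.00175). Of 10 alveolar macrophage markers 2 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.459), and 4 and 1 did without library 1. Chil3 changed by 2.15 (adjusted p = 0.00548) and Cidec by -2.14 (adjusted p = 0.000465). Among 12 neutrophil markers 2 fell (camera adjusted p = 0.921), among 12 B and plasma cell markers 1 rose and 1 fell (camera adjusted p = 0.829), and among 9 mast cell and basophil markers 1 fell (camera adjusted p = 0.661). These counts were the same adjusted over the list alone, and each of them, up or down, was 0 without some single library.

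Of 11 endothelial markers 5 fell in WT (6 adjusted over the list alone), and 3, 2, 2 and 3 did without library 1, 4, 5 or 6. Their camera adjusted p was 0.00168 (adjusted p = 0.241 with an estimated correlation), and Kdr, a VEGF receptor gene, went from 4126 ± 16.8 to 3119 ± 121 (SD, n = 3; adjusted p = 0.00217). Of 9 fibroblast markers 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.000652 (adjusted p = 0.227 with an estimated correlation). The proteoglycan gene Dcn went from 1121 ± 122 to 463 ± 119 (-1.30, adjusted p = 0.00276). Inmt and Tcf21 fell by 1.32 and 0.60 on the log2 scale (adjusted p = 0.00386 and 0.00267), and the microfibril gene Mfap4 rose by 0.51 (adjusted p = 0.00178). Of 8 alveolar type 1 markers 4 fell, or 1 without library 1, 4 or 6, and 1, Pdpn, rose by 0.57 (adjusted p = 0.00693). Adjusted over the list alone, 5 fell and 1 rose, with a camera adjusted p of 0.0261 (adjusted p = 0.341 with an estimated correlation). Of 10 alveolar type 2 markers 2 rose (3 up and 1 down adjusted over the list alone), with a median change of -0.01, a mean of 0.06 and a camera adjusted p of 0.636. The surfactant protein gene Sftpd rose by 0.71 (adjusted p = 0.00121). Of 8 club cell markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.106). Bpifa1, which encodes a secreted airway defence protein, went from 2562 ± 242 to 742 ± 190 (-1.81, adjusted p = 0.0106). Of 10 ciliated cell markers 2 fell, or 1 to 3 with 1 library left out in turn, and 2 adjusted over the list alone, with a camera adjusted p of 0.0215 (adjusted p = 0.227 with an estimated correlation), among them Tppp3 (-0.67, adjusted p = 0.00464). In limma 0 of 7 smooth muscle markers passed (camera adjusted p = 0.533), with 1 higher and 3 lower at an unadjusted p under 0.05. Of 7 erythroid markers 0 passed in limma and 0 had an unadjusted p under 0.05, while camera placed the list below other genes (adjusted p = 0.0103, and adjusted p = 0.381 with an estimated correlation). Of the thymocyte list only 2 genes were tested, too few for camera, of which 0 passed in limma over all genes and 1 was higher adjusted over the list alone.

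**Figure D2:**
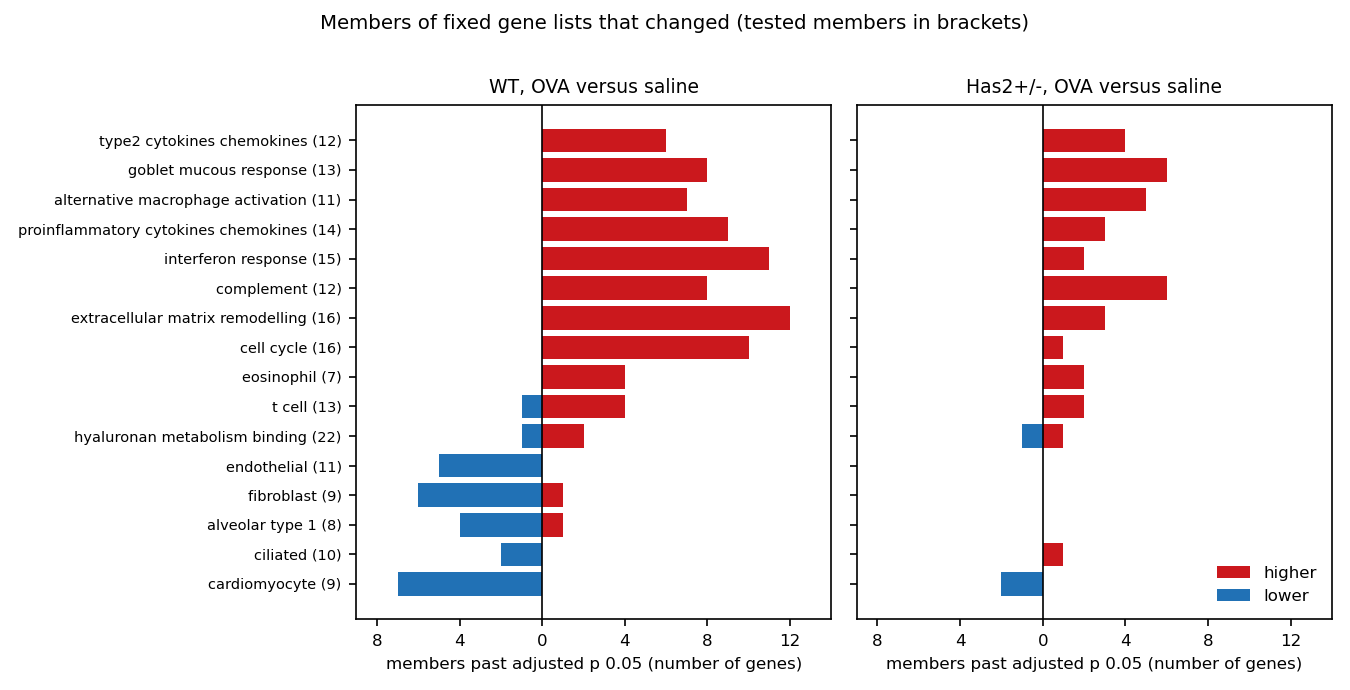
Bars count the members of 16 gene lists that were higher (right of 0) or lower (left of 0) after ovalbumin at adjusted p under 0.05, in WT on the left and in Has2+/- on the right; the number of tested members is in brackets. In WT 12 of 16 matrix genes were higher and 7 of 9 cardiomyocyte genes lower.

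The largest falls in WT included genes of fat cells and metabolism. Adipoq, which encodes the fat cell hormone adiponectin, fell from 273 ± 157 to 15.1 ± 4.15 (SD, n = 3; -3.87, adjusted p = 0.00577). The hormone genes Lep and Retn changed by -3.57 (adjusted p = 0.000654, log2 change -5.91 to -1.29 over 18 alternatives) and -3.54 (adjusted p = 0.00107), and Pck1, of gluconeogenesis, by -3.31 (adjusted p = 0.00648). Car3 (-3.03, adjusted p = 0.00235), Tshr (-2.76, adjusted p = 0.00130) and Cfd (-2.76, adjusted p = 0.00704) fell too. Thrsp, a regulator of fat synthesis, changed by -3.19 (adjusted p = 0.0177), except without library 1, 2, 5 or 6 (adjusted p = 0.0555, 0.0518, 0.0592 and 0.0607, within 0.00802 to 0.0607 over 18 alternatives). Of 9 cardiomyocyte markers 7 fell (9 adjusted over the list alone), with a camera adjusted p of 1.52e-09 (adjusted p = 0.0818 with an estimated correlation). The atrial light chain genes Myl7 and Myl4 changed by -1.39 (522 ± 29.4 to 198 ± 3.22, adjusted p = 8.19e-05) and -1.35 (adjusted p = 0.000578). Ryr2, a calcium channel gene, changed by -1.0 (adjusted p = 8.29e-05). Of 8 markers of fat and skeletal muscle 3 fell, or 7 without library 3 (4 adjusted over the list alone), with a camera adjusted p of 0.000102 (adjusted p = 0.0818 with an estimated correlation).

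Genes of squamous epithelium and skeletal muscle varied widely between libraries of the same group. The mean log2 level of 13 squamous epithelium genes, a list added after the data were seen, was 9.51, 5.61 and 9.19 in the WT saline libraries and 1.21, 0.93 and 9.44 in the WT ovalbumin libraries. In Has2+/- it was 9.69, 9.31 and 2.34 with saline and 3.46, 2.27 and 1.14 with ovalbumin. The skeletal muscle actin gene Acta1 was likewise high in library 3 and low in libraries 1 and 2. In WT it stood at 1738, 573 and 1411 with saline and 0.917, 2.08 and 1617 with ovalbumin. Myh6, the heart muscle myosin gene, had group means of 6183 (WT saline), 2481 (WT ovalbumin), 5673 (Has2+/- saline) and 3633 (Has2+/- ovalbumin). Those of Adipoq were 273, 15.1, 76.1 and 45.2. Of the 13 squamous genes 0 passed in limma in either genotype and 0 had an unadjusted p under 0.05, with a median change of -4.01 in WT. With the squamous level as a covariate, the rises in WT were 4 type 2, 7 goblet, 6 alternative macrophage, 9 proinflammatory, 2 interferon, 9 matrix, 6 cell cycle and 7 complement genes. The median changes of these lists, in this order, were 1.41, 1.37, 1.75, 2.04, 1.93, 0.762, 0.874 and 1.20. In the eosinophil and T cell lists 1 gene each rose. The falls were 8 cardiomyocyte, 5 fibroblast, 3 endothelial and 1 alveolar type 1 genes. Because the squamous level was itself lower in most ovalbumin libraries, the covariate overlaps with treatment and costs precision. Fewer calls with it do not show that another tissue made the changes.

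**Figure D3:**
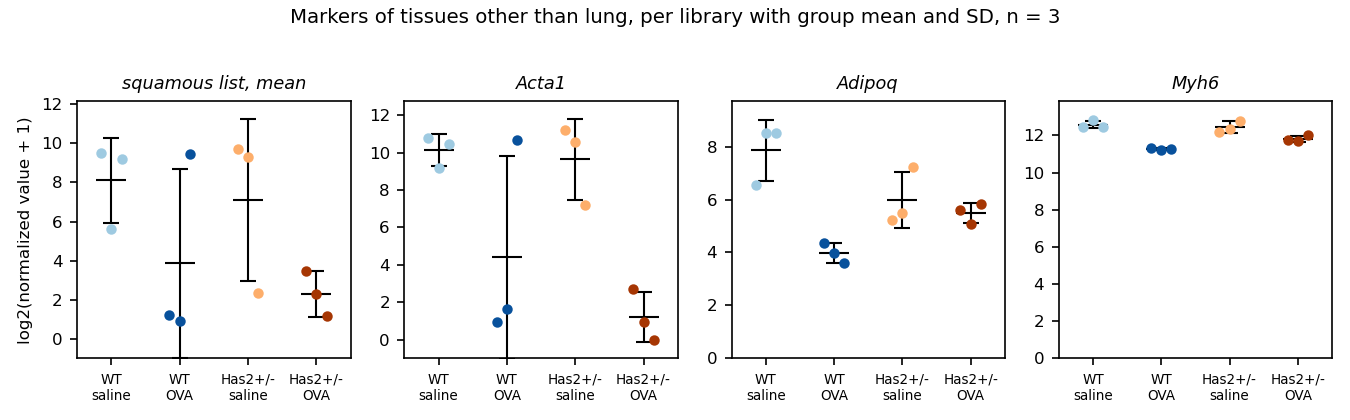
Levels of the squamous epithelium list (mean of 13 genes), Acta1, Adipoq and Myh6 in each library, as log2(normalized value + 1) on the vertical axis by group on the horizontal axis; points are libraries, and lines and bars are the mean and SD of 3 libraries. Library 3, at 9.44, was the only WT ovalbumin library with a high squamous level and library 12, at 2.34, the only Has2+/- saline library with a low one.

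Over all genes, limma called 3175 of 19017 genes in WT, 1645 higher and 1530 lower, of which 497 and 219 changed at least 2-fold. The count was 1653 without library 1, 1808 without library 6 and 1927 with the squamous level as a covariate.

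The same comparison in Has2+/- mice asks how ovalbumin changed the lung transcriptome of the mice labelled so. Chemokine, mucus and macrophage genes again led the rises. Ccl11 went from 21.4 ± 5.05 to 95 ± 19.5 (SD, n = 3; 2.11, adjusted p = 0.00113) and Alox15 from 31.6 ± 6.52 to 92.3 ± 26.7 (1.5, adjusted p = 0.00288). Mrc1 rose from 756 ± 49.6 to 1165 ± 95.4 (0.62, adjusted p = 0.000858) and the neutrophil chemokine gene Cxcl1 from 0.5 ± 0.441 to 9.0 ± 1.2 (2.78, adjusted p = 0.00734). These 4 genes passed in all 18 alternatives, although the log2 change of Cxcl1, with saline values near 0, ran from 0.85 to 4.45. C3 rose from 10669 ± 1624 to 25876 ± 6281 (1.26, adjusted p = 0.00734), Col1a1 from 6936 ± 282 to 10633 ± 1155 (0.61, adjusted p = 0.00505) and Lamp3, an alveolar type 2 cell marker, from 2555 ± 140 to 3352 ± 133 (0.39, adjusted p = 0.00505). The calls of C3, Col1a1 and Lamp3 held whichever single library was left out and each ended in 1 of its 18 alternatives (adjusted p = 0.0554 for C3 with only the groups compared in the fit, within 0.00101 to 0.0554). For Col1a1 and Lamp3 this was limma without its trend and robust options (adjusted p = 0.0668 and 0.0657, within 0.00312 to 0.0668 and 0.00235 to 0.0657).

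Several calls of large changes in Has2+/- rested on single libraries, while the changes themselves stayed in their direction. Over 18 alternatives the log2 change ran from 3.56 to 4.65 for Retnla, 3.37 to 5.21 for Cxcl9, 2.83 to 3.59 for Muc5ac and 2.79 to 3.62 for Fcgbp. Cxcl9 (4.69 ± 1.42 to 159 ± 84.6, SD, n = 3; 4.66, adjusted p = 0.00734) and Cxcl10 (5.89 ± 1.19 to 99.0 ± 68.5, 3.56, adjusted p = 0.0101) rose. So did Ccl8 (3.22, adjusted p = 0.00694) and the monocyte chemokine gene Ccl2 (3.62, adjusted p = 0.00665). None of these 4 passed without library 10, with adjusted p of 0.0550, 0.0662, 0.0527 and 0.0533. Over their 18 alternatives the adjusted p ran from 0.00120 to 0.0550, 7.37e-05 to 0.0662, 0.00211 to 0.0527 and 0.000553 to 0.0567. Muc5ac rose from 76.7 ± 25.4 to 809 ± 259 (3.39, adjusted p = 0.0145), except without library 7, 10 or 11 (adjusted p = 0.0609, 0.0688 and 0.0544, within 0.00194 to 0.0688 over 18 alternatives). Retnla rose from 641 ± 527 to 8837 ± 3041 (4.02, adjusted p = 0.0124), except without the same libraries (adjusted p = 0.0555, 0.0550 and 0.0526, within 0.00108 to 0.0796). Fcgbp, a mucus protein gene, rose by 3.25 (adjusted p = 0.0187), again except without these libraries (adjusted p = 0.0609, 0.0619 and 0.0658, within 0.0146 to 0.0989). Tff2, which encodes a trefoil peptide of mucus, rose by 1.66 (adjusted p = 0.0127), except without library 7 (adjusted p = 0.0609, within 0.00388 to 0.0676). Chil4 rose by 6.04 (adjusted p = 0.0334) and lost its call without library 7, 8, 9, 10 or 11 (adjusted p = 0.130, 0.0686, 0.0568, 0.108 and 0.0881, within 0.00878 to 0.155). Capn9, listed at 0 in the saline libraries, passed with all libraries present (adjusted p = 0.0295) and not without library 9, 10, 11 or 12 (adjusted p = 0.0510 to 0.117, within 0.0130 to 0.248).

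The largest fall in Has2+/- lungs was that of Hamp2, a hepcidin gene, which stood at 61.7 ± 2.40 with saline and was listed at 0 with ovalbumin (SD, n = 3; adjusted p = 1.29e-05). The potassium channel gene Kcna1 went from 33 ± 9.98 to 5.03 ± 1.69 (-2.49, adjusted p = 0.0295), except without library 7, 8, 10 or 11 (adjusted p = 0.149, 0.0626, 0.123 and 0.109, within 0.00469 to 0.149 over 18 alternatives). The other 6 of the 8 largest falls were Asb10, Sim1, Fam221b and Mcpt4, whose calls ended without any of 5 libraries, and Rasgef1c and Slc17a2, whose calls ended without any of the 6, at adjusted p of 0.0604 to 0.189. In the hyaluronan list 1 of 22 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.272). Vcan rose from 233 ± 18.3 to 426 ± 99.3 (0.84, adjusted p = 0.0136), except without library 10 (adjusted p = 0.0760, within 0.000553 to 0.0800 over 18 alternatives). Itih5 fell from 213 ± 36.5 to 95 ± 19.4 (-1.16, adjusted p = 0.0245), except without library 7, 8, 10 or 11 (adjusted p = 0.101, 0.0511, 0.104 and 0.0906, within 0.00232 to 0.104).

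By list, 4 of 12 type 2 genes rose in Has2+/- (5 adjusted over the list alone), with a camera adjusted p of 2.54e-06 (adjusted p = 0.116 with an estimated correlation). Of the goblet list 6 of 13 rose (9 adjusted over the list alone), of the alternative macrophage list 5 of 11 (9) and of the complement list 6 of 12 (10). Their camera adjusted p were 3.34e-11, 3.95e-11 and 3.95e-11 (adjusted p = 0.0770 for each with an estimated correlation). Of the proinflammatory list 3 of 14 rose (9 adjusted over the list alone), of the interferon list 2 of 15 (13), of the matrix list 3 of 16 (9) and of the cell cycle list 1 of 16 (8). Camera gave these lists adjusted p of 5.51e-07, 2.52e-12, 1.29e-07 and 3.85e-05 (adjusted p = 0.218, 0.172, 0.162 and 0.305 with an estimated correlation). Of the 9 cardiomyocyte markers 2 fell (8 adjusted over the list alone), with a camera adjusted p of 4.32e-08 (adjusted p = 0.0770 with an estimated correlation). Ryr2 was among them, from 864 ± 119 to 564 ± 65.3 (SD, n = 3; adjusted p = 0.0104), except without library 7 (adjusted p = 0.0550, within 0.00237 to 0.0816 over 18 alternatives). Of the 10 immediate early genes 2, Nr4a1 and Egr1, fell (3 adjusted over the list alone), with a camera adjusted p of 0.00142 (adjusted p = 0.136 with an estimated correlation). Both lost the call without any 1 of the 6 libraries (adjusted p = 0.0513 to 0.195).

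The counts of these lists rested on single libraries too. Without library 7, 10 or 11, the rises numbered 0, 1 and 1 in the goblet list, 2, 1 and 2 in the type 2 list, 2, 2 and 2 in the alternative macrophage list, and without library 10 or 12 they numbered 1 and 2 in the complement list. The proinflammatory count was 1 and 5 without library 10 or 12, the matrix count 1, 5, 1 and 1 without library 7, 9, 10 or 11, and the interferon, cell cycle and cardiomyocyte counts were 6, 4 and 6 without library 9. With the squamous level as a covariate, 1 goblet, 2 type 2, 2 alternative macrophage, 2 proinflammatory, 1 interferon, 1 matrix and 1 complement gene rose and 3 cardiomyocyte genes fell. The median changes of these lists, in this order, were 1.35, 1.02, 1.34, 0.911, 1.42, 0.271, 0.731 and -0.688. Here too the covariate overlaps with treatment.

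In total 532 genes passed in Has2+/-, 351 higher and 181 lower, of which 117 and 22 changed at least 2-fold. The count was 103, 288, 51 and 115 without library 7, 8, 10 or 11, 934 without libraries 3 and 12, and 67 with the squamous level as a covariate. The share of higher genes was 66.0%, and 77.2% of 425 genes with the trend on transcript GC content and length removed.

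**Figure D4:**
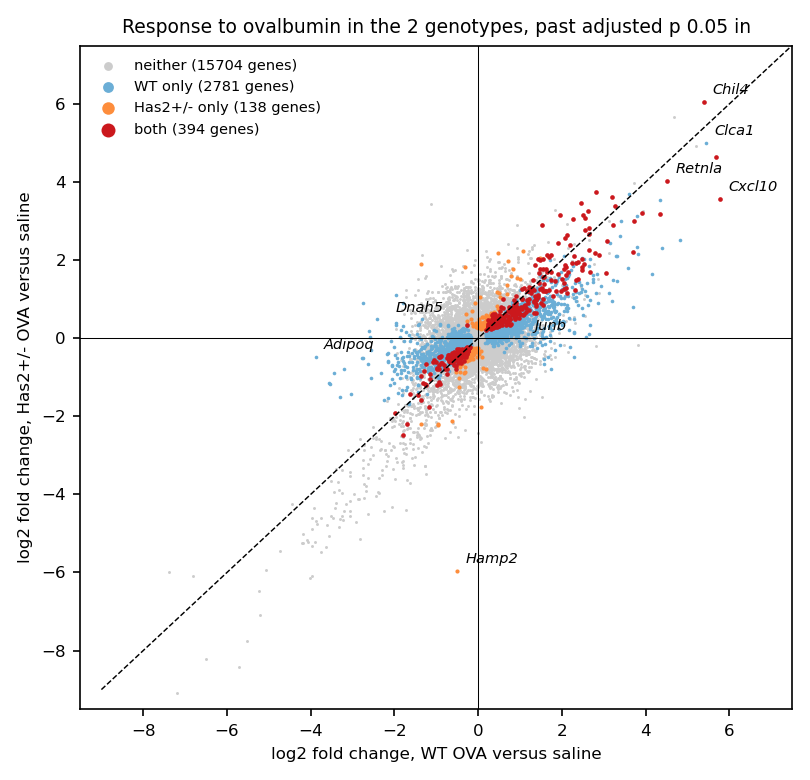
Log2 change after ovalbumin in WT (horizontal axis) and in Has2+/- (vertical axis) for 19017 genes, coloured by where they passed adjusted p 0.05; each point is a gene and the dashed line marks equal change. The 394 genes that passed in both lie on the same side of 0 in both genotypes except Dnah5.

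The responses of the 2 genotypes shared many genes. Of the genes called, 393 changed in the same direction in WT and Has2+/-, 272 higher (30.4 expected if the calls were independent) and 121 lower (14.6 expected). The ciliary motor gene Dnah5 was called in opposite directions, at -0.27 in WT (SE 0.08, adjusted p = 0.0355) and 0.35 in Has2+/- (SE 0.08, adjusted p = 0.0385), with an interaction of 0.62 (adjusted p = 0.281). The call in WT ended without library 1, 3, 4 or 6 (adjusted p = 0.127, 0.0581, 0.0960 and 0.162, within 0.0297 to 0.517 over 18 alternatives). That in Has2+/- ended without library 8, 9, 10 or 11 (adjusted p = 0.101, 0.0835, 0.152 and 0.139, within 0.00573 to 0.177). Across the 19017 genes, which are not independent replicates, the changes had a Pearson r of 0.640 and a slope of Has2+/- on WT of 0.610. With a group mean of at least 5 required, the slope was 0.715. Error in the WT changes pulls such a slope toward 0, so it does not measure a weaker response in Has2+/-. The 2 comparisons share no library. The overlap was 254, 246, 235, 89, 238, 43 and 102 genes without library 4, 5, 6, 7, 8, 10 or 11. It was 59 with the squamous level as a covariate and 716 without libraries 3 and 12, where the balance turned to 321 higher and 395 lower. A larger number of calls in WT does not show that the responses differ, which is what the interaction tests.

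The third comparison asks what the genotype changed in saline-treated lungs. In limma 2 genes passed, both higher in Has2+/-, and 1069 had an unadjusted p under 0.05. Hamp2 (ENSMUSG00000056978, chromosome 7, 30922389 to 30924681), one of the mouse hepcidin genes, stood at 0.611 ± 1.06 in WT and 61.7 ± 2.40 in Has2+/- (SD, n = 3; 5.47, adjusted p = 4.74e-05). Clec2d (ENSMUSG00000030157, chromosome 6, 129180615 to 129186534), which encodes a C-type lectin that binds a receptor of natural killer cells, stood at 726.5 ± 48.8 and 1113 ± 56.1 (0.62, adjusted p = 0.00184). Since Hamp2 was near 0 in WT, its log2 change depended on the pseudocount and ran from 2.76 to 7.85 over 18 alternatives. Each kept its call without any single library and in 17 of its 18 alternatives, with adjusted p of 9.35e-09 to 0.120 and of 0.000501 to 0.0781. No member of any list passed in limma over all genes. Adjusted over the list alone, 4 immediate early genes were higher and 1 lower, with a camera adjusted p of 0.00218 (adjusted p = 0.276 with an estimated correlation). In the ciliated list 3 genes were lower adjusted over the list alone, with a camera adjusted p of 2.76e-06 (adjusted p = 0.109 with an estimated correlation). Camera placed the erythroid list higher, with an adjusted p of 6.57e-06 (adjusted p = 0.327 with an estimated correlation), and Hbb-bs, a beta globin gene, stood at 12672 ± 4312 against 8224 ± 674. The fat and skeletal muscle list was placed lower, with an adjusted p of 0.000769 (adjusted p = 0.229 with an estimated correlation). The count of genes was 8 without library 4, 4 without library 12, 4 without libraries 3 and 12, and 12 with only the 2 groups in the fit.

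The fourth comparison asks what the genotype changed in ovalbumin-treated lungs. Clec2d was higher in Has2+/- and genes of the immediate early response were lower. Clec2d stood at 487 ± 21.3 in WT and 1005 ± 63.7 in Has2+/- (SD, n = 3; 1.04, adjusted p = 1.73e-06) and was called in all 18 alternatives. Of 10 immediate early genes 4 were lower, also adjusted over the list alone, and 1 was without library 8. The list had a camera adjusted p of 0.0144 (adjusted p = 0.470 with an estimated correlation). Junb, which encodes a subunit of the AP-1 transcription factor, stood at 1577 ± 213 and 882 ± 113 (-0.84, adjusted p = 0.00563). Ier2 (-0.57, adjusted p = 0.00750) and Jun (-0.34, adjusted p = 0.0120), the gene of another AP-1 subunit, were lower as well. Without library 8 the adjusted p of Ier2 was 0.0553 and that of Jun 0.0563 (within 0.00675 to 0.0804 and 0.00820 to 0.145 over 18 alternatives). With the GC and length trend removed they were 0.0606 and 0.0648. Zfp433, a zinc finger gene, was higher (37.4 ± 2.60 against 81.2 ± 5.83, 1.10, adjusted p = 0.00458). The calls of Junb and Zfp433 held without any single library but ended in 2 and 1 of their 18 alternatives. Ppp1r3c, whose product directs a phosphatase to glycogen, was higher (42.9 ± 4.96 against 89.2 ± 7.25, 1.04, adjusted p = 0.00807), except without library 8 (adjusted p = 0.0563, within 0.00562 to 0.0735). Csrnp1 was lower (141 ± 32.9 against 67.8 ± 3.45, -1.02, adjusted p = 0.0120), except without library 8 or 9 (adjusted p = 0.0563 and 0.0576, within 0.00877 to 0.0882). The linker histone gene Hist1h1e was lower (-0.91, adjusted p = 0.0120), except without library 1 or 8 (adjusted p = 0.0502 and 0.0644, within 0.00664 to 0.0671).

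Other genes at the top of this comparison passed only with most libraries present. The dendritic cell genes Cd207 (1.36 ± 1.19 in WT against 10.4 ± 4.40 in Has2+/-, SD, n = 3; adjusted p = 0.0425) and Cd209a (19.2 ± 1.98 against 45.6 ± 10.6, adjusted p = 0.0220) were higher. Cd207 lost its call without library 1, 3, 8 or 9 (adjusted p = 0.0624, 0.109, 0.184 and 0.166, within 0.0151 to 0.203 over 18 alternatives) and Cd209a without library 1, 2, 8 or 9 (adjusted p = 0.0601, 0.0568, 0.0681 and 0.123, within 0.0136 to 0.130). Ptgs2, which encodes the inducible cyclooxygenase, was higher (42.4 ± 0.210 against 89.5 ± 24.8, 1.02, adjusted p = 0.0366). Without library 1, 2, 3 or 8 it did not pass (adjusted p = 0.0913, 0.0718, 0.0766 and 0.153, within 0.0305 to 0.153). Per1, a clock gene that glucocorticoids induce, was lower (1862 ± 185 against 968 ± 107, -0.94, adjusted p = 0.0253). Without library 1, 2, 3, 8 or 9 its call ended (adjusted p = 0.0848, 0.0520, 0.0630, 0.103 and 0.0651, within 0.00866 to 0.103). In the hyaluronan list 1 of 22 genes was higher, also adjusted over the list alone (camera adjusted p = 0.718). This was Tmem2 (also named Cemip2), the gene of a cell-surface hyaluronidase, at 2086 ± 145 against 2619 ± 235 (0.33, adjusted p = 0.0366). Its call ended without library 1, 3, 8 or 9 (adjusted p = 0.116, 0.0749, 0.0565 and 0.149, within 0.0200 to 0.214). Mybphl, Zfp52, Gpr3, Bmp10 (listed at 0 in Has2+/-), Rhov, Cldn4 and Ccdc184 were also among the largest changes, each lost without 3 to 5 single libraries at adjusted p of 0.0502 to 0.166.

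Of 16 matrix genes 1, the collagen gene Col5a1, was lower in Has2+/- after ovalbumin (1 up and 5 down adjusted over the list alone). With 1 library left out in turn, 0 to 4 were lower. The call of Col5a1 ended without library 2, 3, 8 or 9 (adjusted p = 0.0932, 0.0634, 0.142 and 0.138, within 0.0115 to 0.181 over 18 alternatives). The matrix list had a camera adjusted p of 0.000497 (adjusted p = 0.470 with an estimated correlation). Of 13 glucocorticoid genes 1, Per1, was lower (1 up and 5 down adjusted over the list alone), with a camera adjusted p of 0.0106 (adjusted p = 0.470 with an estimated correlation). Of the TGF-beta list 0 genes passed in limma, with 1 higher and 4 lower at an unadjusted p under 0.05 (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.345). Of 9 cardiomyocyte genes 1, Myl7, was higher in Has2+/- (4 adjusted over the list alone) and of 7 erythroid genes 0 (1 adjusted over the list alone). The call of Myl7 (0.79, adjusted p = 0.0169) ended without library 1, 2, 3 or 9 (adjusted p = 0.0708, 0.0520, 0.0543 and 0.0756, within 0.00947 to 0.0955 over 18 alternatives). Camera placed these lists higher, with adjusted p of 0.000606 and 0.000497 (adjusted p = 0.470 for both with an estimated correlation).

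In all, 181 genes passed in limma, 112 higher and 69 lower in Has2+/-, 10 and 4 of them by at least 2-fold. The transcripts of the higher genes had a median GC content of 42.6% and those of the lower genes 57.7%, against 50.04% for all tested genes. With the trend on GC content and length removed 34 genes passed, 29 of them among the 181, including Clec2d, Junb, Zfp433, Ppp1r3c, Csrnp1 and Hist1h1e. The count was 55, 107, 92, 774, 17 and 39 without library 1, 2, 3, 7, 8 or 9 and 41 without libraries 3 and 12. It was 7 with only the 2 groups in the fit and 10 without limma's trend and robust options. The share of higher genes was 61.9%, and 83 of 170 with median-of-ratios rescaling.

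The interaction asks whether ovalbumin acted differently in the 2 genotypes. Junb rose after ovalbumin in WT, from 712 ± 29.9 to 1577 ± 213, and stood at 884 ± 99.3 and 882 ± 113 in Has2+/- (SD, n = 3; interaction -1.14, SE 0.16, adjusted p = 0.0331). Muc16, which encodes a membrane mucin, fell in WT from 576 ± 51.3 to 311 ± 28.2 and stood at 458 ± 17.3 and 457 ± 56.1 in Has2+/- (0.88, SE 0.14, adjusted p = 0.0481). Hamp2 fell in Has2+/- and stood at 0.611 ± 1.06 in WT saline libraries (-5.47, SE 0.67, adjusted p = 0.00627). In limma these 3 genes passed, against 1625 with an unadjusted p under 0.05. The call of Junb ended without library 1, 3, 4, 5, 6, 8, 9, 10 or 11 (adjusted p = 0.0621, 0.120, 0.128, 0.0753, 0.180, 0.186, 0.0976, 0.114 and 0.0598, within 0.00366 to 0.186 over 23 alternatives). That of Muc16 ended without any single library except 7 (adjusted p = 0.0753 to 0.257, within 0.00904 to 0.257). That of Hamp2 ended without library 10 or 11 (adjusted p = 0.0563 and 0.0543, within 1.48e-06 to 0.295), and its log2 difference ran from -7.85 to -2.76 over 23 alternatives. The number of genes was 0 without library 10 or 11, 1 without library 1, 3, 5, 6, 8 or 9, and 25 without library 7.

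Of the immediate early genes 1, Junb, passed in the interaction (0 up and 5 down adjusted over the list alone), with a camera adjusted p of 1.41e-06 (adjusted p = 0.0594 with an estimated correlation). The ciliated list went the other way (2 up adjusted over the list alone), with a camera adjusted p of 1.41e-06 (adjusted p = 0.0594 with an estimated correlation). The matrix list was down (5 down adjusted over the list alone), with a camera adjusted p of 1.41e-06 (adjusted p = 0.314 with an estimated correlation). The cardiomyocyte list was up in the interaction as well, with a camera adjusted p of 3.24e-05 (adjusted p = 0.225 with an estimated correlation).

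**Figure D5:**
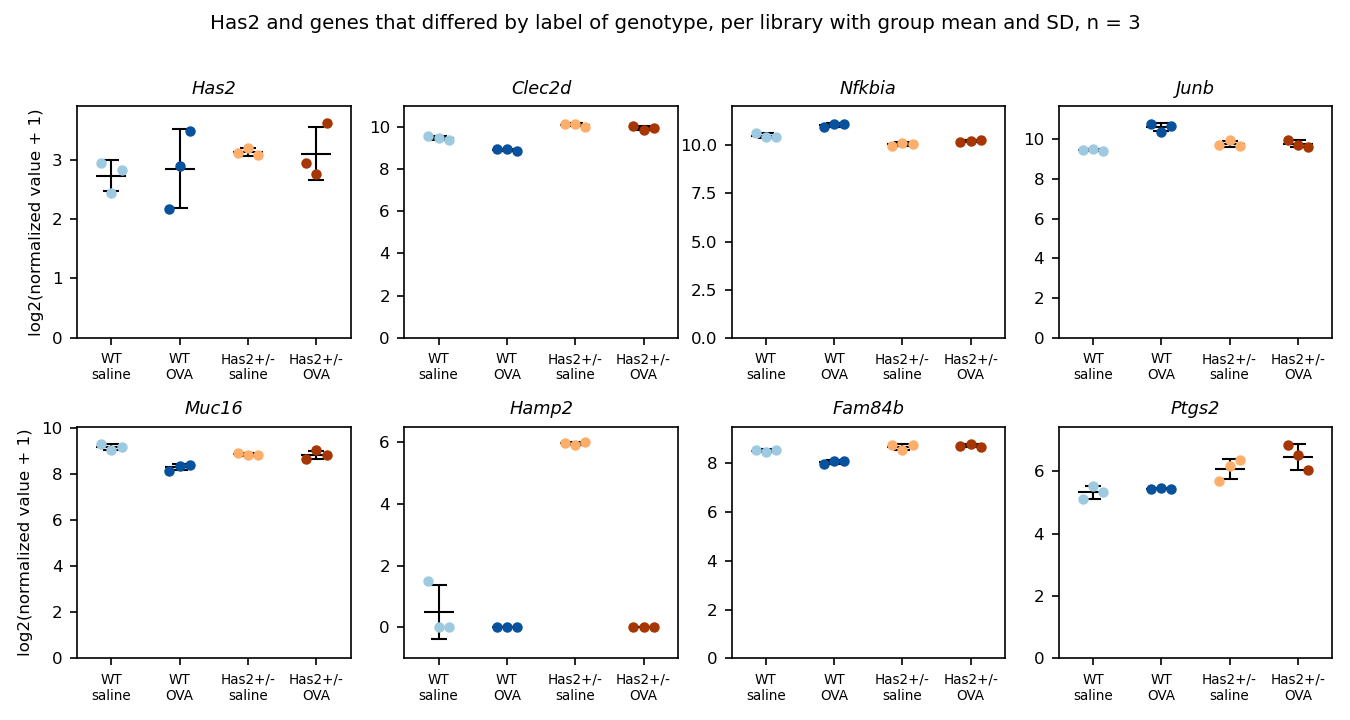
Normalized values of Has2, Clec2d, Nfkbia, Junb, Muc16, Hamp2, Fam84b and Ptgs2 in the 12 libraries, as log2(value + 1) on the vertical axis and the 4 groups on the horizontal axis; points are libraries, and lines and bars are the mean and SD of 3 libraries. Clec2d stood at 1113 and 1005 in the Has2+/- groups against 726.5 and 487 in WT.

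The last comparison averages the genotype difference over both treatments, 6 libraries against 6. Clec2d was higher in Has2+/- by 0.83 (adjusted p = 2.84e-07). Nfkbia (ENSMUSG00000021025, chromosome 12, 55489411 to 55492647), which encodes the inhibitor that holds NF-kappa-B in the cytoplasm, was lower (-0.63, adjusted p = 1.25e-05). It stood at 1458 ± 129 and 2138 ± 134 in WT with saline and ovalbumin and at 1073 ± 65.4 and 1211 ± 43.0 in Has2+/- (SD, n = 3). Clec2d, Nfkbia and Zfp433 (0.73, adjusted p = 0.00591) passed in all 23 alternatives. Whichever single library was left out, though not in 1 or 2 of the 23 alternatives, Ctnnd2, a catenin gene, was higher (0.64, adjusted p = 0.0101), and Csrnp1 (-0.81, adjusted p = 0.00906), the corepressor gene Irf2bp2 (-0.41, adjusted p = 0.00591) and Jun (-0.29, adjusted p = 0.00547) were lower. Ptgs2 was higher (0.89, adjusted p = 0.0159), except without library 4, 8, 11 or 12 (adjusted p = 0.0527, 0.0590, 0.0515 and 0.0592, within 0.00975 to 0.0956 over 23 alternatives). The zinc finger gene Zfp790 was higher (0.48, adjusted p = 0.0141), except without library 8 or 12 (adjusted p = 0.0505 and 0.0502, within 0.00747 to 0.0905). Smad7, which encodes an inhibitor of TGF-beta signalling, was lower (-0.32, adjusted p = 0.0357), except without library 2, 3, 4, 5, 6, 9, 10, 11 or 12 (adjusted p = 0.0559 to 0.112, within 0.0217 to 0.188). Phlda3 was lower (-0.38, adjusted p = 0.0141), except without library 6, 8 or 11 (adjusted p = 0.0508, 0.0505 and 0.0513, within 0.00747 to 0.0956). Zfp52, Zfp235, Zfp950, Per1, Nr2f6, Adrm1 and Ier2 passed with all libraries and lost the call without 6 to 10 of them.

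By list, 7 erythroid genes were higher adjusted over the list alone, 0 in limma over all genes and 7 at an unadjusted p under 0.05. That list had a camera adjusted p of 1.11e-06 (adjusted p = 0.397 with an estimated correlation). Of the glucocorticoid list 1 gene, Per1, was lower (1 up and 5 down adjusted over the list alone), with a camera adjusted p of 0.000867 (adjusted p = 0.397 with an estimated correlation). Of the TGF-beta list 1 gene, Smad7, was lower, also adjusted over the list alone (camera adjusted p = 0.376). In the hyaluronan list 0 of 22 passed in limma over all genes, 2 had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone (camera adjusted p = 0.453). In total 80 genes passed in limma, 43 higher and 37 lower. The count was 46, 32, 39, 33, 259, 19, 45, 25, 28 and 26 without library 3, 4, 5, 6, 7, 8, 9, 10, 11 or 12. It was 18 without libraries 3 and 12, and 34 with the GC and length trend removed (median GC content 44.5% for the higher genes and 56.9% for the lower). The share of higher genes was 53.8%, and 40 of 92 with median-of-ratios rescaling.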

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

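The comparison of the ovalbumin effect between the genotypes was planned; the tests on Hamp2 and the other splits of the libraries were chosen after the result was seen. In 3 genes the ovalbumin effect differed between WT and Has2+/- by the interaction test in limma.

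The hepcidin gene Hamp2 had a log2 difference of the ovalbumin effects of -5.47 (adjusted p = 0.00627). It stood at 62.1, 59.2 and 63.9 normalized units in the 3 Has2+/- saline libraries, at 1.83 in WT saline library 4, and was listed at 0 in the other 8 libraries. Reads shared with its neighbouring copy Hamp are argued against, because the sum of both genes was at least 69.3 in the Has2+/- saline libraries and at most 17.75 elsewhere, a ratio of 3.90, where a shift of reads between the copies would keep the sum. Liver or pancreas in these samples is argued against as well: among 11 marker genes of these tissues the highest mean in the Has2+/- saline libraries was 8.31 (Apoa1), below the 61.7 of Hamp2. A property that these 3 libraries share by handling, which the labels give no batch to test, stays open, as does a difference of genotype that is seen without ovalbumin.

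Junb, the AP-1 subunit, had a difference of -1.14 (adjusted p = 0.0331): it was higher after ovalbumin in WT by 1.14 and changed by -0.01 in Has2+/- (adjusted p = 0.990). Muc16, the membrane mucin, had a difference of 0.88 (adjusted p = 0.0481): it was lower after ovalbumin in WT by -0.89 and changed by -0.01 in Has2+/- (adjusted p = 0.975).

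Of 100 splits of the 12 libraries for the interaction, 4, the real one included, called at least 3 genes. This does not exclude chance for the 3 genes, because the other splits mix the genotype difference into the spread within groups, and the real count was 0 without library 10 or 11 and 1 with median-of-ratios rescaling or with the GC and length trend removed. The highest other count, 80, came from the split of libraries 4 to 9 against the rest, whose interaction is by construction the genotype difference averaged over treatments, so that it repeats the 80 genes of that comparison and adds no evidence.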

How the results depend on the processing

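The settings with the squamous covariate, without libraries 3 and 12, with median-of-ratios rescaling, tie averaging, a pseudocount of 10 and the GC and length trend removed, and all the splits below, were chosen after the result was seen; the other alternatives were planned. No named gene that passed changed direction, but 2 of the 3175 genes called for ovalbumin in WT did with the GC and length trend removed. Has2, named by rule, passed in no comparison. Its sign changed over the alternatives for ovalbumin in WT (-0.203 to 0.458) and in Has2+/- (-0.282 to 0.285). It also changed for genotype under ovalbumin (-0.0886 to 0.572) and the interaction (-0.483 to 0.177). With median-of-ratios rescaling the balance of calls turned, from 112 higher and 69 lower to 83 and 87 for genotype under ovalbumin and from 43 and 37 to 40 and 52 for the average. Of the named genes that passed, 68 of 102 (ovalbumin in WT), 5 of 54 (ovalbumin in Has2+/-), 0 of 2 (genotype under saline), 1 of 26 (genotype under ovalbumin), 0 of 3 (interaction) and 3 of 18 (average) passed under each of the 18 alternatives (23 for the interaction and the average) applied to single genes, which leave out the requirement of a log2 change of at least 1. Quantile normalization in limma moved nothing, because the values were already quantile-normalized, and so tested nothing, although it is counted among the 18 and 23 alternatives. No paired analysis was possible because the columns of the table carry no replicate numbers, and the replicate block was therefore not run.

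With a log2 change of at least 1 required, the counts were 716, 139, 1, 14 and 3 genes for ovalbumin in WT, ovalbumin in Has2+/-, genotype under saline, genotype under ovalbumin and the average, and 111 for the overlap, fewer by construction. With the squamous level as a covariate they were 1927 and 67 for ovalbumin in WT and Has2+/- and 59 for the overlap. Without libraries 3 and 12 they were 934 for ovalbumin in Has2+/-, 4 and 41 for genotype under saline and ovalbumin, 0 for the interaction, 18 for the average and 716 for the overlap. Without the trend and robust options they were 51, 5, 10, 5 and 9 for ovalbumin in Has2+/-, genotype under saline, genotype under ovalbumin, the interaction and the average, and 42 for the overlap. Without a filter they were 350 for ovalbumin in Has2+/- and 105 for genotype under ovalbumin, and with the stricter filter 0 for the interaction. A pseudocount of 0.1 gave 1 for genotype under saline and 0 for the interaction. Fits of only the groups compared gave 12 and 7 for genotype under saline and ovalbumin. Removal of the GC and length trend gave 34 for genotype under ovalbumin, 1 for the interaction and 34 for the average, and median-of-ratios rescaling gave 1 for the interaction. Leaving out 1 library in turn gave 1653 to 3349 genes for ovalbumin in WT, 51 to 709 for ovalbumin in Has2+/-, 2 to 8 for genotype under saline, 17 to 774 for genotype under ovalbumin, 0 to 25 for the interaction, 19 to 259 for the average and 43 to 569 for the overlap; where this left a group with 2 libraries, its spread was taken from the pooled fit. Apart from the fold requirement, the cause was not tested.

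In other splits of the 6 libraries of a comparison, 10 in all, the real one was the only 1 of the 10 to call as many genes: 3175 against at most 0 for ovalbumin in WT, 532 against 0 for ovalbumin in Has2+/-, 2 against 0 for genotype under saline and 181 against 14 for genotype under ovalbumin; 10 splits cannot give a share under 0.05. For the average, 1 of 100 splits, the real one, gave 80 genes and the highest other 6. That share is under 0.05, which goes against chance for the count as a whole if genotype changed nothing. It covers no single gene among the 80. It also cannot tell genotype from handling that differed between these libraries, for which the labels give no batch. The depth of each library is unknown, but genes with 10 reads sat at a mean of 8.49 to 12.6 units, depending on the library. Has2 ran from 3.5 to 11.25 units over the libraries, so it rested on few reads in each. Counting error is therefore a sizable part of its value and of other genes at such values, and no interval was computed for it.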

Other observations

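The tests of the squamous, muscle and heart genes, of zinc finger genes and of genes near Has2 were chosen after the result was seen; the test of GC content was written before. Some genes of the fixed lists outside the naming rule were also chosen after their values were seen. Il33, an epithelial alarmin that activates type 2 lymphoid cells, rose in WT from 413 ± 27.6 to 1006 ± 155 (SD, n = 3; log2 change 1.27, adjusted p = 0.0136) and in Has2+/- from 409 ± 144 to 981 ± 289 (1.27, adjusted p = 0.0467). Its call ended in WT without library 1 or 6 (adjusted p = 0.0606 and 0.0516; 7.42e-05 to 0.0606 over 18 alternatives) and in Has2+/- without library 7, 8, 10 or 11 (0.157, 0.0894, 0.160 and 0.143; 0.00482 to 0.191). Muc5b, the mucin of healthy airways, rose in WT from 3182 ± 440 to 6885 ± 1527 (1.10, adjusted p = 0.00881), in all 18 alternatives, and in Has2+/- from 3218 ± 504 to 7846 ± 1349 (1.28, adjusted p = 0.0205), except without library 7, 10 or 11 (0.0980, 0.0871 and 0.0838; 0.00111 to 0.0980). The type 2 cytokine genes themselves sat near the lower end of the scale: Il13 went from 0.667 ± 0.577 to 6.42 ± 4.88 in WT (1.95, adjusted p = 0.0306), a call that ended without library 1, 3, 4, 5 or 6 (0.163, 0.0756, 0.122, 0.0521 and 0.0596; 0.00821 to 0.163), and stood at 1.31 ± 0.529 and 2.22 ± 1.30 in Has2+/- (adjusted p = 0.738), while Il5 stood at 5.83 ± 1.88 and 4.69 ± 2.77 in WT (adjusted p = 0.669).

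Antibody genes varied between the libraries of a group after ovalbumin. Jchain, which links antibody multimers, stood at 922, 454 and 23.4 in the WT ovalbumin libraries and at 829, 55.3 and 386 in the Has2+/- ovalbumin libraries, against group means of 96.03 ± 30.9 and 57.2 ± 17.5 with saline (SD, n = 3; adjusted p = 0.612 and 0.439). Ighm, the heavy chain of IgM, stood at 6836, 4020 and 1395 and at 3461, 1675 and 3776 in the same libraries. Library 3, with the lowest value of both genes among the WT ovalbumin libraries, was the one with a high squamous level.

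In the deposited test results 1712 genes had an FDR under 0.05 for ovalbumin in WT, 471 for ovalbumin in Has2+/-, 7 for genotype under saline and 70 for genotype under ovalbumin. Of these, limma called 1623, 256, 2 and 48, all in the same direction. The direction of the deposited fold changes rests on reading them as the second group named against the first, an order the headers do not state. The balance of the calls was another: 1115 higher and 597 lower in the deposited results against 1645 and 1530 in limma for ovalbumin in WT, 277 and 194 against 351 and 181 for ovalbumin in Has2+/-, 4 and 3 against 2 and 0 for genotype under saline, and 24 and 46 against 112 and 69 for genotype under ovalbumin.

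Squamous epithelium and skeletal muscle genes were lower in most ovalbumin libraries, by -4.24 in WT and -4.82 in Has2+/- in the mean log2 level of the squamous list. All 17 genes tested, 13 squamous and 4 of skeletal muscle, were higher in library 3 than in both other libraries of its group and lower in library 12 than in both others of its group, an order for which these genes and libraries were picked, so that pieces of a tissue other than lung in some libraries stay open as a source. Krt4, the most abundant, reached 13669 in library 3 and 17649 in library 10 and was at 48.7 in library 12, and 4 of the 13 genes were at 10 units or more in the Has2+/- ovalbumin group, which had low squamous levels. With treatment permuted within genotype (400 arrangements), the two-sided exact permutation p of the squamous level was 0.05, at the threshold. That test asks only whether the level goes with treatment. It cannot tell a lowering by ovalbumin from uneven dissection, and dissection is recorded for no library. Krt4 was high in library 3, given ovalbumin, and low in library 12, given saline, so treatment alone does not set the level of each library. The same tissue is argued against as the source of the heart genes that fell in WT, because with the squamous level as a covariate all 7 of the 7 cardiomyocyte genes were still called lower (median change -1.19 before and -1.43 after, median standard error 0.15 before), while the calls over all genes went from 3175 to 1927; separate dissection of heart, an effect of ovalbumin and the source of the fat genes stay open.

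The 181 genes that differed by genotype under ovalbumin followed transcript GC content. The Spearman correlation of change and GC content was -0.28 across genes, which are not independent, and with the trend removed 29 of the 181 (16.02%) were still called in the same direction. The median absolute change of the 181 went from 0.47 to 0.37, while its median standard error went from 0.0872 to 0.0891. Smaller changes were not separated from the shift of the adjusted threshold as the reason the calls ended. A bias by GC content may account for part of the list, though not for Clec2d (0.97 with the trend removed, adjusted p = 6.47e-06, within 1.59e-06 to 0.00124 over 18 alternatives). Zinc finger genes, symbols beginning with Zfp or Zkscan, made up 15 of the 112 higher genes (13.4%). They were 384 of 18905 other tested genes (2.03%, two-sided Fisher's exact p = 1.27e-08). This test takes genes as independent, which they are not, so its p does not measure the spread between libraries. However, over all zinc finger genes the median GC content was 45.2%. With the trend removed 2 of the 15, Zfp433 and Zfp790, were still called, while the median change of all zinc finger genes went from 0.22 to 0.15. The genotype itself, as a biological cause of a shift that follows GC content, stays open and was not tested.

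A hypothesis on the genes that differed by genotype in the average is that some may be carried along with the targeted allele, as DNA that flanks Has2. Within 20 Mb of Has2, a window chosen after the result was seen, lay 4 of the 80 genes called (5%) against 196 of 18937 others (1.04%; two-sided Fisher's exact p = 0.0101). These were Mal2 (0.31, adjusted p = 0.0141), Fam84b (0.41, adjusted p = 0.00547), Oxr1 (0.26, adjusted p = 0.0450) and Fzd6 (0.53, adjusted p = 0.0110), at -2.09, 4.15, -15.2 and -17.7 Mb from Has2 and all higher in Has2+/-. Of the 80 genes called, 9 lay on chromosome 15, that of Has2, inside or outside the window. Because the window was set with the called genes in view, the Fisher's exact p above is no independent test of the hypothesis. It also takes genes as independent, which they are not. With the GC and length trend removed, 27 of the 80 genes kept their call. How the calls of the 4 genes held in the alternatives is not given here. Sequence variants that would mark flanking DNA were not analysed here, and the labels name the same strain for both genotypes.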
